A study of Drosophila melanogaster with 6 samples.

How the data were processed

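RNA from eye-antennal discs of wandering 3rd instar larvae, raised at 25 °C, was measured on 6 single-colour Affymetrix arrays, 3 of GMR-Gal4 with UAS-RasV12 and 3 of GMR-Gal4 with UAS-sSpi. Per the labels' protocols, each sample was 100 discs collected into Trizol, and biotin-labelled cRNA was made from 5 ug of total RNA. The deposited values are intensities, 1 MAS5-type signal per probe set on a linear scale. MAS5 is named in the submitters' processing notes, and its version is not given in the sources used here. Every array had a mean of 100 after trimming 2% from each end, so the authors' intensities had been scaled to 1 common level. No genome build is named. The table held 14010 probe sets per array, and columns were matched to samples by the table's own sample names, with 0 columns left unmatched.

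Gene names came from the platform's annotation table. Of 13966 probe sets without the 44 controls, 12443 had 1 gene symbol, 327 had several and 1196 had none, and only probe sets with 1 symbol were named. The symbols of 12394 were updated through gene identifiers to the gene table of assembly Release 6 plus ISO1 MT, which was used for names and for which genes neighbour each other. The single-symbol probe sets stood for 10844 genes.

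Signals were taken as log2(signal + 16). The pseudocount keeps MAS5 noise at low signal from dominating, and it shrinks the fold of dim genes. The 60% of probe sets with the highest mean signal over all 6 arrays were tested, 8380 probe sets of 6768 named genes with mean signals above 23.4. Differences are RasV12 minus sSpi, fitted per probe set with lmFit and eBayes with a mean-variance trend in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Values are means ± SD of the signal over 3 arrays, and log2 differences carry the standard error of the fit. The number of arrays limits the precision.

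Before the data were examined, 28 gene lists, the rule for named genes, the tests and the alternatives were fixed. The alias Delta was added afterwards to the gene Dl, because the reference table uses that symbol and the older one was ambiguous. Of 462 list symbols, 313 had a single-symbol probe set and 259 were tested; the others are unnamed here or lay below the signal filter. A list was represented by 1 probe set per gene, the brightest over all arrays, and 26 lists with at least 3 tested members were tested as sets with camera at a preset correlation of 0.01, adjusted over the lists. The named genes are Ras85D, spi, Egfr and w, the 12 largest differences in each direction among genes past the threshold whose groups did not overlap, and up to 4 members of each list past the threshold, or the 2 with the smallest p where none passed. List scores per array and a few further genes were added after the values were seen.

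The fit was tested on simulated data built from the 8380 probe sets of RasV12 against sSpi, in 5 simulations with 200 changed probe sets each. It recovered 26.0% of those changed by a log2 value of 0.5, 80.3% at 1 and 97.0% at 2, and 4.38% of calls were false. With no change, 1 of 20 simulations made a call. In simulated lists of 12 genes, camera found 50 of 50 lists shifted by a log2 value of 0.4 and 5 of 50 unshifted lists at an unadjusted p of 0.05. The simulated genes varied independently of each other, and no simulated array deviated as a whole. These counts therefore do not measure errors for lists whose genes vary together, nor false calls where an array stands apart.

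The titles give both genotypes replicate numbers 1 to 3. Arrays that share a number did not deviate together, so the numbers were not taken as pairs. The alternatives fixed in advance were pseudocounts of 1 and 64, no signal filter, the upper 40% of probe sets, quantile normalization, median scaling, eBayes without the trend, the replicate number as a block, each array left out in turn, 1 probe set per gene, camera with a correlation estimated from the data and the fry test. After seeing the data, a fit without RasV12 replicate 1 and sSpi replicate 2 and a fit with the ecdysone list score as a covariate were added. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.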

Results

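Transcript levels were measured in eye-antennal imaginal discs, the larval epithelia that give rise to the adult eye and antenna of Drosophila melanogaster. GMR-Gal4, a driver active in eye disc cells behind the morphogenetic furrow, the moving front at which photoreceptor differentiation starts, expressed 1 of 2 transgenes. RasV12 is an activated form of the small GTPase Ras, which acts inside the cell that makes it. sSpi is a secreted form of Spitz, the ligand that activates the EGF receptor upstream of Ras. There were 3 arrays per genotype, 6 in all, each from 100 discs of wandering larvae, and the titles call the arrays of a genotype biological replicates. No array of discs without a transgene was analysed here, so each value compares 1 genotype with the other. The description of the sSpi samples names RasV12, whereas their titles, sources and genotypes name sSpi; the arrays were grouped by title.

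The 6 arrays had median signals from 39.4 to 41.4. Pearson's r across 8380 probe sets lay between 0.961 and 0.983 within RasV12, between 0.971 and 0.978 within sSpi and between 0.948 and 0.967 across genotypes. The first principal component held 38.1% of the variance and parted the genotypes, with scores of 12.5 to 12.8 for RasV12 and -19.6 to -8.47 for sSpi. The second component held 24.9% and set RasV12 replicate 1, at 20.3, apart from the other arrays, which lay between -13.4 and 3.93. The same array had a signal of 157 for the middle probe set of 18S ribosomal RNA, against 24.7 to 30.4 on the other 5. The ratio of 3' to 5' signal for the Gapdh control lay between 2.83 and 3.26 on all 6 arrays.

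The comparison of RasV12 with sSpi asks which transcripts differ when the pathway is driven by activated Ras inside the cell or by a secreted ligand at the receptor. In RasV12 discs, SoxN, which encodes a SoxB transcription factor of neural development, was 4.19-fold higher. The Runx factor gene lz, needed in photoreceptor and cone cell precursors, was 3.74-fold higher, and the homeobox gene B-H1 2.54-fold. The FGF ligand gene ths was 2.61-fold higher and Dad, which encodes an inhibitory Smad of the Dpp pathway, 2.50-fold. In sSpi discs, kek1 and sty, which encode feedback inhibitors of EGF receptor signalling, were 1.86-fold and 1.83-fold higher, and Ilp8, a relaxin-like peptide made by discs with disturbed growth, was 2.71-fold higher. Each of these 8 genes had an adjusted p under 0.05 (limma, n = 3 per genotype), and folds are on the log2(signal + 16) scale, which understates the change of dim genes.

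Of 8380 probe sets tested, 219 passed an adjusted p of 0.05 in limma, 109 higher and 110 lower in RasV12. They stood for 188 named genes, 91 higher and 97 lower, and 65 of the 219 differed by a log2 value of at least 1, 34 higher and 31 lower. The median absolute log2 difference of the 219 was 0.79. The count moved with the array left out: without RasV12 replicate 1 it was 369, without RasV12 replicate 2 it was 106, without RasV12 replicate 3 it was 150, and without sSpi replicates 1, 2 or 3 it was 98, 86 or 134. Without both RasV12 replicate 1 and sSpi replicate 2, a choice made after seeing the data, 162 passed, of which 121 were among the 219. The call of each named gene was repeated in 15 or 16 other settings, with other processing, with arrays left out, or with the ecdysone list score of each array as a covariate, which was also chosen after seeing the data.

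Among the 12 largest differences higher in RasV12, SoxN rose from a signal of 25.2 ± 5.26 in sSpi to 158 ± 32.1 in RasV12 (SD, n = 3), a log2 difference of 2.07 ± 0.17 (SE, limma adjusted p = 0.00055). The lz signal was 188 ± 33.6 in RasV12 and 39.9 ± 18.2 in sSpi, a log2 difference of 1.90 ± 0.22 (limma adjusted p = 0.0025, n = 3). CG31676 reached 443 ± 82.4 against 104 ± 17.3 and fipi, an immunoglobulin-domain gene, 347 ± 44.6 against 121 ± 6.75, with log2 differences of 1.93 ± 0.15 and 1.40 ± 0.12. The signal of ths was 164 ± 3.57 against 53.2 ± 8.29, a log2 difference of 1.39 ± 0.12 (limma adjusted p = 0.00077, n = 3). The serpin gene Spn43Aa was at 990 ± 402 in RasV12 and 273 ± 114 in sSpi. Its call ended in 4 of 16 other settings, without RasV12 replicate 2, sSpi replicate 2, both doubted arrays (RasV12 replicate 1 and sSpi replicate 2) or the signal filter, at adjusted p up to 0.074. The methuselah-like receptor gene mthl8 and CG14180 lay near background in sSpi, with signals of 3.72 ± 3.71 and 4.86 ± 0.75, and at 50.8 ± 1.88 and 60.4 ± 24.5 in RasV12. The other 4 were CG9416, flap, CG6357 and the UDP-glycosyltransferase gene Ugt302K1, with log2 differences from 1.43 to 1.70.

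Among the 12 largest differences lower in RasV12, CG4306 and Uhg1, a host gene of small nucleolar RNAs, lay near background in RasV12, at 2.14 ± 0.63 and 1.73 ± 0.52, against 97.6 ± 21.4 and 75.0 ± 22.0 in sSpi (SD, n = 3). Both passed (limma adjusted p = 0.00035 and 0.00055), while the size of such a difference depends on the pseudocount: that of CG4306 was -1.28 with a pseudocount of 64 and -4.97 with 1. The C-type lectin gene slf fell from 337 ± 83.6 in sSpi to 66.5 ± 17.7 in RasV12, a log2 difference of -2.09 ± 0.21 (limma adjusted p = 0.0012, n = 3). CG14275 measured 59.2 ± 14.3 in RasV12 and 283 ± 41.4 in sSpi, and CG15522 measured 65.3 ± 23.6 and 261 ± 55.2. The metalloprotease gene AdamTS-B measured 96.2 ± 10.9 in RasV12 and 289 ± 10.1 in sSpi, and Ilp8 measured 41.6 ± 17.1 and 137 ± 16.1. The cytochrome P450 gene Cyp4g15 was at 8.74 ± 3.71 in RasV12 and 58.0 ± 3.09 in sSpi. Tmtc2 was at 14.8 ± 4.64 and 56.7 ± 7.02. CG7900, CG13606 and the odorant-binding protein gene Obp56d completed the 12, with log2 differences from -1.49 to -1.33.

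**Figure D1:**
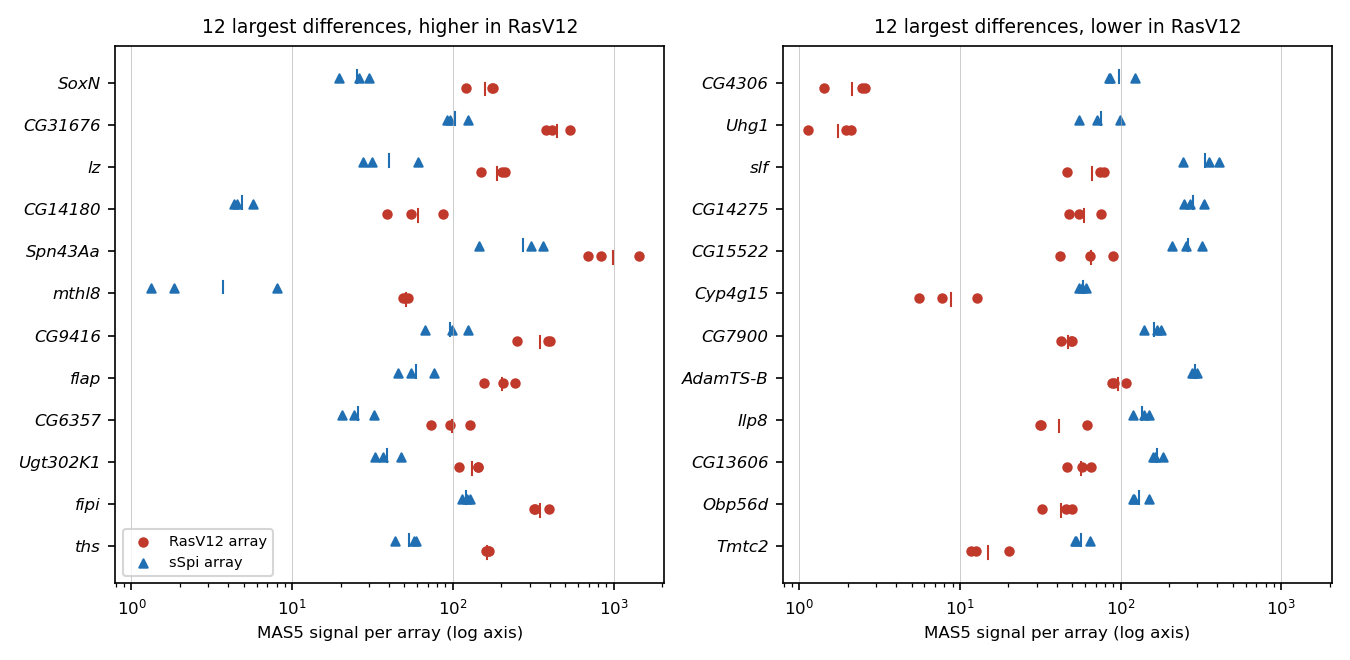
Signal of each array (log axis, MAS5 signal units) for the 12 genes with the largest differences higher in RasV12 (left) and lower in RasV12 (right); circles are the 3 RasV12 arrays, triangles the 3 sSpi arrays, and short vertical lines the group means. The rule of selection required that the 3 values of a genotype do not overlap those of the other. Means in RasV12 and sSpi were 158 and 25.2 for SoxN, and 2.14 and 97.6 for CG4306.

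The transgene-matched genes were examined as a check of the labels. The spi probe set measured 1018 ± 25.8 in RasV12 and 1314 ± 83.6 in sSpi (SD, n = 3), a log2 difference of -0.36 ± 0.09 that did not pass (limma adjusted p = 0.082). All 3 sSpi values were the higher ones, with an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow. After quantile normalization between arrays the difference was -0.35 and passed, with a limma adjusted p of 0.037. A probe set that lies outside the transgene would check nothing, and its position was not analysed here. Ras85D, the gene of the RasV12 transgene, and w had no probe set with a single gene symbol and are unnamed here.

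Among EGF receptor and Ras target genes, 2 of 8 tested fell in RasV12 and none rose, over all genes and adjusted over the list alone. The list fixed 14 genes, of which pnt, rho, ru, vn, Socs36E and Ets21C were not tested. The kek1 signal was 71.0 ± 8.09 in RasV12 and 146 ± 17.2 in sSpi, a log2 difference of -0.90 ± 0.13 (limma adjusted p = 0.0059, n = 3). The sty signal was 250 ± 42.3 and 474 ± 91.5, a log2 difference of -0.88 ± 0.16 (limma adjusted p = 0.020, n = 3), and its call ended in 6 of 16 other settings, without RasV12 replicates 2 or 3, sSpi replicates 1 or 2 or the signal filter and with the ecdysone covariate, at adjusted p up to 0.089. Other targets did not pass, among them aos, which encodes a secreted antagonist of the receptor, at a log2 difference of 0.18 ± 0.15, and Delta, at 0.19 ± 0.13. The list EGFR/Ras target genes did not pass as a set in the main analysis (camera adjusted p = 0.10), with an adjusted p of 0.74 with an estimated correlation. It passed in 2 of 18 other settings, without sSpi replicate 3 (0.032) and with the ecdysone covariate (0.016), which ended the call of sty, 1 of the 2 genes called. Of 11 pathway components, Egfr itself rose, from 211 ± 17.5 in sSpi to 356 ± 43.7 in RasV12, a log2 difference of 0.71 ± 0.12 (limma adjusted p = 0.014, n = 3). Adjusted over the list alone, 1 component was higher, Egfr, and 1 lower, spi. The second Egfr probe set gave 0.33 ± 0.12 and did not pass (adjusted p = 0.22), and the call of the first ended without sSpi replicate 1 (0.073) or sSpi replicate 3 (0.055). The pathway list as a set did not pass (camera adjusted p = 0.46).

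Genes of photoreceptor specification moved in both directions. Of 15 tested, 3 rose and 2 fell in RasV12, and adjusted over the list alone 4 rose and 3 fell. With lz, B-H1, which specifies the R1 and R6 photoreceptors, rose from 102 ± 24.2 to 281 ± 41.0, a log2 difference of 1.35 ± 0.17 (limma adjusted p = 0.0037, n = 3). The proneural gene ato, which selects the founding R8 photoreceptor, rose from 207 ± 21.8 to 461 ± 37.7, a log2 difference of 1.10 ± 0.11 (limma adjusted p = 0.0012, n = 3). The nuclear receptor gene svp, active in outer photoreceptors, fell from 215 ± 8.40 in sSpi to 111 ± 14.1 in RasV12, a log2 difference of -0.87 ± 0.11 (limma adjusted p = 0.0047, n = 3), and its second probe set also passed at -0.76 ± 0.12. The homeobox gene ro fell as well, with a log2 difference of -0.61 ± 0.12. The list as a set did not pass (camera adjusted p = 0.56). Of 7 genes of cone, pigment and interommatidial cells, 2 rose, lz and B-H1, which the list shares with the one before, and adjusted over the list alone 3 rose and 1 fell; the set did not pass (camera adjusted p = 0.34). Of 10 retinal determination genes, 1 fell, ey, a Pax6 gene, at -0.48 ± 0.11, with a limma adjusted p of 0.048. Its call ended in 13 of 16 other settings, among them quantile normalization, median scaling, the replicate block, the ecdysone covariate and each single array left out other than RasV12 replicate 1, at adjusted p up to 0.21. Adjusted over the list alone, 1 of these 10 rose and 1 fell, and the set did not pass (camera adjusted p = 0.79).

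Of 13 Notch pathway genes and E(spl) targets, 2 rose in RasV12, E(spl)m2-BFM and Brd, both of the Bearded family of Notch pathway antagonists, and none fell. Their log2 differences were 0.74 ± 0.12 and 0.73 ± 0.15 (SE, limma adjusted p = 0.012 and 0.040, n = 3). Adjusted over the list alone, 5 rose and 1 fell. The 1 that fell was E(spl)malpha-BFM, also of the Bearded family, at -0.35 ± 0.11. Ocho, also of the Bearded family, had 2 probe sets, of which the one that stood for the list did not pass, at 0.42 ± 0.12 (adjusted p = 0.12), while the other did, at 0.99 ± 0.16 (0.014); it was singled out after its values were seen. The list median was 0.30, with 11 of 13 differences above 0, and the set passed (camera adjusted p = 0.0011), with an adjusted p of 0.32 with an estimated correlation. Each RasV12 array had a list score, the mean log2 deviation of the genes from their mean over 6 arrays, above each sSpi array, at 0.08 to 0.19 against -0.16 to -0.11. The call of E(spl)m2-BFM ended in 3 of 16 other settings, without RasV12 replicate 2 or sSpi replicates 1 or 2, with adjusted p up to 0.067. That of Brd ended in 8 of 16, without any single array other than RasV12 replicate 3 or sSpi replicate 3, without both doubted arrays, the signal filter or the trend in eBayes, and with the replicate block, with adjusted p up to 0.18. Of 9 furrow and patterning genes, 1 rose, Dad, from 76.4 ± 20.3 to 214 ± 43.1, also adjusted over the list alone, while dpp, the ligand of its pathway, differed by -0.21 ± 0.16; the set did not pass (camera adjusted p = 0.99).

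**Figure D2:**
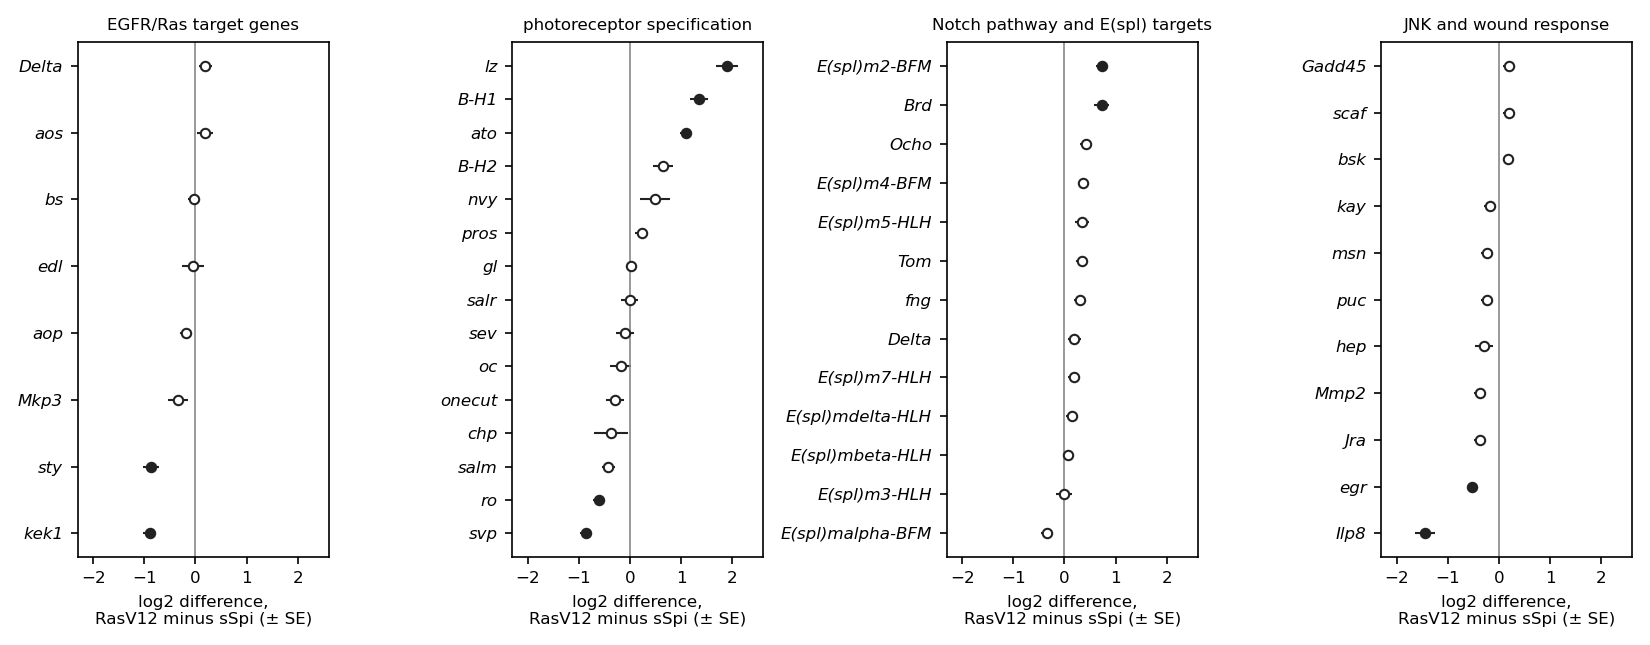
Log2 difference, RasV12 minus sSpi, of each tested gene of 4 gene lists; points are estimates from 3 arrays per genotype, bars are standard errors, and filled points passed an adjusted p of 0.05. In photoreceptor specification lz (1.90), B-H1 (1.35) and ato (1.10) lie to the right and ro (-0.61) and svp (-0.87) to the left, and among target genes sty (-0.88) and kek1 (-0.90) lie to the left.

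Genes of the JNK and wound response were lower in RasV12 for 2 of 11 tested, Ilp8 and egr, the Drosophila tumour necrosis factor, and none rose. The Ilp8 log2 difference was -1.44 ± 0.19 (limma adjusted p = 0.0051, n = 3) and that of egr -0.53 ± 0.10 (limma adjusted p = 0.024, n = 3), whose call ended in 7 of 16 other settings, without any single array other than RasV12 replicate 1, without both doubted arrays and with the replicate block, at adjusted p up to 0.11. Adjusted over the list alone, 4 fell. The set passed with a median of -0.24 (camera adjusted p = 0.020), with an adjusted p of 0.74 with an estimated correlation. RasV12 replicate 1 had the lowest list score, -0.24, against -0.09 and -0.08 in the other RasV12 arrays and 0.10 to 0.18 in sSpi, and the list JNK and wound response did not pass without it (adjusted p = 0.12) or without both doubted arrays (0.25). Of 7 apoptosis genes 2 fell, egr, which both lists hold, and grim, a cell death activator, also adjusted over the list alone. The grim log2 difference was -0.80 ± 0.17 (limma adjusted p = 0.042, n = 3), and its call ended in 9 of 15 other settings, among them each single array left out other than RasV12 replicate 1, no signal filter, the replicate block and the ecdysone covariate, at adjusted p up to 0.17. The apoptosis list had a median of 0.04 and a mean of -0.12 and did not pass (camera adjusted p = 0.54).

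Neuronal differentiation genes were lower in RasV12 for 1 of 13, Nrg, a cell adhesion molecule of the L1 family, at 460 ± 9.29 against 694 ± 44.9 (limma adjusted p = 0.013, n = 3). Its call ended in 4 of 16 other settings, without RasV12 replicate 2, sSpi replicate 2 or sSpi replicate 3 and with the replicate block, at adjusted p up to 0.072. Adjusted over the list alone, 1 rose and 5 fell. The list median was -0.25, with 10 of 13 differences below 0, and the set passed (camera adjusted p = 0.020), with an adjusted p of 0.74 with an estimated correlation. The list score was -0.31 in RasV12 replicate 1, against -0.03 and 0.0025 in the other RasV12 arrays, and without that array the set did not pass (adjusted p = 0.15). The list neuronal differentiation missed the threshold in 6 of 18 other settings, among them both doubted arrays left out (0.25), no signal filter (0.057) and the upper 40% of probe sets (0.051). The pan-neuronal gene elav differed by -0.10 ± 0.11. Of the 4 tested probe sets of Ank2, 1 passed at 0.62 ± 0.13, against the direction of the other 3, which lay between -0.54 and -0.40; this gene was singled out after its values were seen.

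None of 14 genes of the response to ecdysone, the steroid that times metamorphosis, passed over all genes in limma, while 5 had an unadjusted p under 0.05 and 2 passed adjusted over the list alone, both higher in RasV12. The list median was 0.41, with 12 of 14 differences above 0, and the set passed (camera adjusted p = 0.011), with an adjusted p of 0.74 with an estimated correlation. The 2 were Cth, at 306 ± 18.3 in RasV12 and 221 ± 31.9 in sSpi, and ImpE3, at a log2 difference of 1.61 ± 0.44 (limma adjusted p = 0.10 and 0.11 over all genes, n = 3). The list score differed among RasV12 arrays, at -0.33 in replicate 1 and 0.50 and 0.57 in replicates 2 and 3, and was -0.04, -0.15 and -0.56 in sSpi replicates 1 to 3. The set did not pass without RasV12 replicate 2 (adjusted p = 0.064) or RasV12 replicate 3 (0.065).

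**Figure D3:**
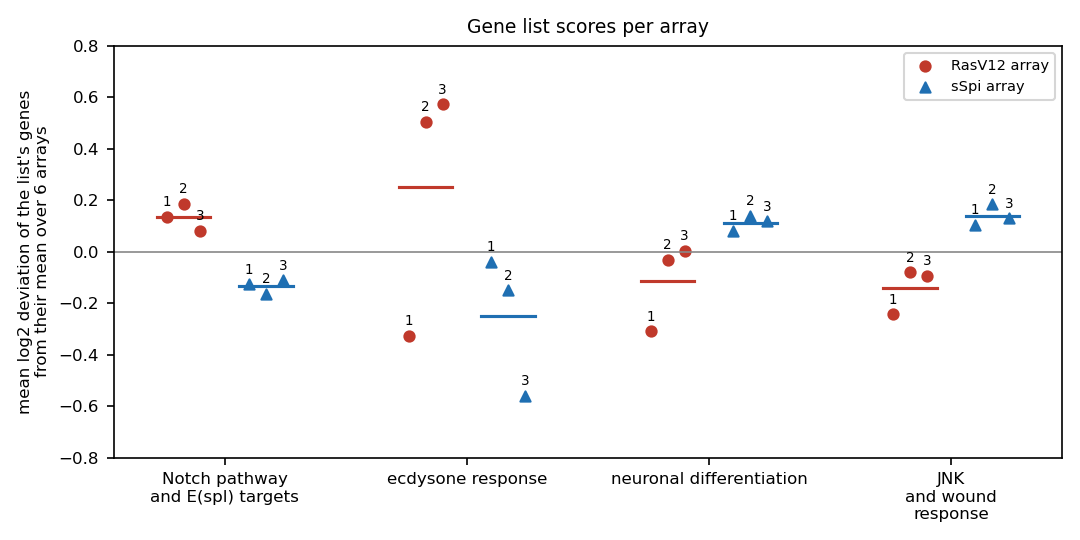
List score of each array, the mean log2 deviation of a list's genes from their mean over the 6 arrays, for 4 lists; circles are RasV12 arrays, triangles sSpi arrays, small digits the replicate number and horizontal lines the group means. The Notch and E(spl) scores of RasV12 (0.08 to 0.19) lie above those of sSpi (-0.16 to -0.11), while the ecdysone score of RasV12 replicate 1 (-0.33) lies far below those of replicates 2 and 3 (0.50 and 0.57).

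Of 11 glial genes 1 fell in RasV12, Gli, which encodes a septate junction protein, from 1189 ± 39.8 to 738 ± 43.0, a log2 difference of -0.68 ± 0.09 (limma adjusted p = 0.0051, n = 3). Adjusted over the list alone, 2 glial genes rose and 4 fell, 7 had an unadjusted p under 0.05, and the glial transcription factor gene repo differed by -0.30 ± 0.15. No gene of 9 plasmatocyte markers, the macrophage-like blood cells, passed in limma, over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05. Of 6 crystal cell and lamellocyte markers 1 rose, lz, which blood and eye cells share. Of 12 basement membrane genes 1 rose, Ppn, at 0.59 ± 0.13, with a limma adjusted p of 0.0498, and its call ended in 13 of 16 other settings, among them each of the 6 arrays left out, at adjusted p up to 0.18. Of 6 immune genes 1 fell, nec, a serpin gene of the Toll pathway, at 12.3 ± 3.29 in RasV12 and 49.6 ± 8.99 in sSpi (limma adjusted p = 0.0059, n = 3). Of 8 antennal identity genes B-H1 rose and the homeobox genes al and Lim1 fell, at -1.09 ± 0.16 and -0.70 ± 0.14. The call of this Lim1 probe set ended in 8 of 16 other settings, without any single array other than RasV12 replicate 1, without both doubted arrays or the signal filter and with the replicate block, at adjusted p up to 0.11, while another Lim1 probe set differed by -1.14 ± 0.16 (limma adjusted p = 0.0053). Adjusted over each list alone, lz, Ppn and nec were called in their lists, and 3 antennal genes rose and 2 fell. An unadjusted p under 0.05 was found for 5 antennal, 3 crystal cell and lamellocyte, 2 basement membrane and 1 immune gene. The camera adjusted p of these 6 lists lay between 0.46 and 0.99.

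No gene of 9 disc margin and peripodial epithelium markers passed in limma, while 6 had an unadjusted p under 0.05 and, adjusted over the list alone, 4 rose and 1 fell. Their median was 0.31, and the set passed only without RasV12 replicate 1 among the single arrays left out (camera adjusted p = 0.026, against 0.078 with all 6), with an adjusted p of 0.74 with an estimated correlation. Of 19 cell cycle genes 0 passed and 1 had an unadjusted p under 0.05, and the PCNA signal was 682 ± 154 in RasV12 and 822 ± 63.8 in sSpi. No gene of 8 glycolytic and 8 Myc and nucleolar genes passed in limma or had an unadjusted p under 0.05. Of 32 ribosomal protein genes 0 passed and 1 had an unadjusted p under 0.05, and 28 lay below 0 with a median of -0.10. In these 4 lists 0 genes passed adjusted over the list alone. The ribosomal set did not pass (camera adjusted p = 0.055), with an adjusted p of 0.99 with an estimated correlation. It passed in 2 of 18 other settings, without RasV12 replicate 1 (0.0064) or sSpi replicate 1 (0.00015), at the preset correlation of 0.01. Of 8 heat shock and detoxification genes 1 rose, Hsp27, at 0.51 ± 0.10, with a limma adjusted p of 0.034, also adjusted over the list alone. Its call ended in 11 of 16 other settings, among them the replicate block and each single array left out other than RasV12 replicate 1, at adjusted p up to 0.14. The camera adjusted p of the cell cycle, glycolysis, Myc and heat shock lists lay between 0.18 and 0.99.

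Of 8 muscle genes 1 rose in RasV12, sls, the titin gene, at a log2 difference of 0.82 ± 0.14 (limma adjusted p = 0.014, n = 3), also adjusted over the list alone. Its call ended in 4 of 15 other settings, without RasV12 replicate 2, sSpi replicates 1 or 2 or both doubted arrays, at adjusted p up to 0.070. The list muscle did not pass as a set (camera adjusted p = 0.54), with an adjusted p of 0.99 with an estimated correlation. It passed in 2 of 18 other settings, without sSpi replicate 3 (0.028) and with the ecdysone covariate (0.016), and its score was -0.45, -0.22 and 0.49 in sSpi replicates 1 to 3. No gene of 4 larval brain, 3 salivary gland and cuticle or 2 fat body genes passed or had an unadjusted p under 0.05, over all genes or adjusted over the list alone. The 2 fat body genes, Fbp1 and Lsp2, stood at 98.1 and 137 in sSpi replicate 1. On the other arrays they reached at most 24.9 and 61.7, and the cause was not tested. The salivary glue protein gene Sgs7 measured 21.4 ± 11.9 in RasV12 and 93.6 ± 148 in sSpi, where replicate 2 alone was at 265. Without that array the salivary set was higher in RasV12, with a median of 0.49 (camera adjusted p = 0.041). With all arrays its median was -0.48 (camera adjusted p = 0.63, and 0.99 with an estimated correlation). The reversal rests on 3 genes, of which Sgs3 and Sgs7 passed the signal filter only through sSpi replicate 2. On the other arrays they reached at most 20.8 and 35.1, so no difference between genotypes is drawn from it. The larval brain set did not pass (camera adjusted p = 0.40). The 2 dosage compensation RNAs had no single-symbol probe set.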

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

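The ecdysone covariate and the fit without both RasV12 replicate 1 and sSpi replicate 2 were chosen after seeing the data. Of 44 named genes past the threshold, 31 passed in the same direction in every other setting that tested them, and none reversed. The 219 probe sets past the threshold became 138 without a signal filter (70 higher and 68 lower), of which 119 were among the 219. With the ecdysone covariate 340 passed (216 lower). Without both of those arrays 71 were lower, and with the replicate block 70 were higher. Leaving out 1 array gave 86 to 369, with 41 to 202 higher and 45 to 167 lower. Of the 65 with a log2 difference of at least 1, a pseudocount of 64, which shrinks differences, left 19 (11 higher and 8 lower), and the covariate gave 118 (77 lower). The spi difference passed after quantile normalization, at -0.35, and in no other setting. The 4 lists past the threshold became 2 without both of those arrays, 0 in camera with an estimated correlation, where 1 list had an unadjusted p under 0.05, and 1 with fry. For the list salivary gland and cuticle, the median reversed to 0.49 without sSpi replicate 2, where Sgs3 and Sgs7 had mean signals below the filter. It was -0.98 without sSpi replicate 3. Unless a reason is given, the cause was not tested. Arrays sharing a replicate number had deviations from their group means correlated at -0.11, -0.04 and -0.14, and with the number as a block 159 probe sets passed, 147 of them among the 219. Probe sets with mean signals under 23.4 were not tested, which limits what can be said of dim genes.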

Other observations

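The splits of the arrays were planned, and every other test below was chosen after the result it bears on was seen. The genes of this paragraph were singled out from their values. In RasV12 discs, both FGF8-like ligand genes, ths and pyr, its neighbour among the tested genes, were higher. The pyr signal was 88.5 ± 15.7 against 33.3 ± 4.19 (SD, n = 3), a log2 difference of 1.08 ± 0.15 (limma adjusted p = 0.0055). The receptor gene htl was at 46.3 ± 6.21 against 22.6 ± 4.80, a log2 difference of 0.69 ± 0.16 that did not pass over all genes (adjusted p = 0.055). Of 22 cytochrome P450 genes, Cyp4e2 rose, at 200 ± 41.7 in RasV12 and 80.9 ± 8.59 in sSpi, while Cyp4p1 and Cyp4p2 fell, with log2 differences of -1.02 and -1.22, as did Cyp4g15, near background in RasV12. Among 22 gene families defined by their symbols after the largest differences had been seen, 0 passed in camera as a set and 2 had an unadjusted p under 0.05, the UDP-glycosyltransferases (adjusted p = 0.090) and the cytochromes P450 (0.36).

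In 10 splits of the 6 arrays into 3 and 3, the real split gave 219 probe sets past the threshold and 65 with a log2 difference of at least 1, each in 1 of the 10, and the highest of the others gave 0 and 0. For gene lists the real split gave 4 and the highest of the others 6, and 4 of the 10 splits gave at least 4. The splits are too few for a share under 0.05. Every other split also puts arrays of both genotypes in each group. A difference between the genotypes then adds to the spread within groups and lowers the count, so the 0 does not show what chance alone would give. The 2 splits that gave 6 lists put RasV12 replicate 1 with sSpi replicate 3 and 1 further sSpi array.

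In sSpi replicate 2, salivary glue genes were high: ng3 was at 769 against at most 9.56 on the other 5 arrays, Sgs3 at 140 against at most 20.8, and the uncharacterised CG12310 at 2210 against at most 16.7. Of 8 glue genes, of which the 6 Sgs genes are also in the salivary list, 7 were highest in that array, and Sgs1, at 15.8, was not. These genes were looked at because they were high there, so the count tests no explanation, and the cause, technical or biological, stays open.

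The ecdysone genes had a group difference in list score of 0.50, with an exact two-sided permutation p of 0.3 (n = 3 per genotype, smallest possible 0.1), and spanned 0.90 within RasV12 alone. Discs from larvae of different stage within a genotype could give such a span. The span within RasV12 rests on replicate 1, whose 18S ribosomal RNA signal was 157, against 24.7 to 30.4 on the other arrays. A technical cause was not tested. Within sSpi the score spanned 0.52. In RasV12 replicate 1, 10 of the 14 genes lay below both other RasV12 arrays. An effect of genotype on developmental timing stays open and was untested. With the score as a covariate, 169 of the 219 calls stayed past the threshold, and 340 probe sets passed in all. This cannot decide whether stage caused calls. A probe set that followed the score would vary within RasV12, and would seldom be among the 219.

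The 219 calls include 7 genes near background, under a signal of 16, on every array of 1 genotype and over 32 on every array of the other, nec, CG4306, Uhg1 and Cyp4g15 in RasV12 and mthl8, CG14180 and CG15550 in sSpi. Such genes led to the hypothesis that the transgenic stocks differ in stretches of chromosome, which may add calls unrelated to the transgenes. Neighbours were here taken as genes next to each other on a chromosome among the 6748 tested genes with a known position, whatever untested genes lie between. Among 176 called genes with a known position, 6 neighbouring pairs changed in the same direction, against a median of 2 and a 95th percentile of 5 in 10000 permutations (one-sided permutation p = 0.025). The test was first meant for the genes near background and was then run on all called genes, and 2 of the pairs hold such a gene. Without these genes 170 called genes and 4 pairs were left, against the same median and 95th percentile (one-sided permutation p = 0.17), so that stretches of chromosome that differ between the stocks stay open. The 6 pairs were Tsp42El and lbm, Cyp4p2 and Cyp4p1, pyr and ths, mthl8 and Pdk1, grim and CG4306, and ro and T48. The pairs of related genes could equally be regulated together, and an effect of the transgenes stays open too.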
